A study of Mus musculus with 24 samples.

How the data were processed

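Gene expression was measured in the hearts of male wild-type C57Bl/6 mice, 8 weeks old, kept in a cycle of 12 h light and 12 h dark. Per the labels, hearts were collected at 6 zeitgeber times (ZT, hours after lights-on) spaced by 4 h, snap frozen in liquid nitrogen, and extracted for total RNA with TRIzol. Biotin-labelled cRNA made from 500 ng of RNA was hybridised to Affymetrix mouse gene arrays, 1 array per sample. Each time point held 4 arrays that the labels call biological replicates, 24 arrays in all. Samples were grouped by the time point in their labels, and replicate numbers name arrays only.

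The deposited table gives 1 value per probe set and array, which was read as a log2 value. The base of the logarithm is not stated and base 2 is an assumption, so every fold change given here rests on it. Higher values were taken as more RNA, which is not stated either. Summarisation, background correction, normalization and software are not given in the sources used here. In the deposited values the median of each probe set over the 24 arrays is 0 within 5e-07, so each log2 value is a difference from the gene's own median and no expression level is kept. Dim genes could therefore not be told from bright ones, and no signal over background is known. Values ran from -2.18 to 3.33, and array medians from -0.00223 to 0.00731. The medians of replicates 1 to 4 were -0.00123, -0.00187, -0.000864 and -0.000835 at ZT03, -0.00139, -0.00121, 0.000863 and 0.000856 at ZT07, 0.000218, -0.00188, -0.000663 and -0.000241 at ZT11. In the dark they were 0.00731, 0.00101, -0.000319 and 0.0033 at ZT15, -0.000615, 0.00014, -0.000435 and -0.000701 at ZT19, -0.00223, 0.000755, 0.000841 and 0.00388 at ZT23. The SD of all probe sets on an array lay between 0.103 and 0.171, with the highest values in ZT15 replicate 1 (0.171), ZT23 replicate 4 (0.155) and ZT07 replicate 4 (0.153). Correlations between arrays ran from -0.292 to 0.282, and no pair of arrays held the same values. Of 34351 probe sets, 931 shared all values with another probe set.

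Of the 34351 probe sets, 23521 named 1 gene, 1814 named several and 9016 named none in the platform annotation. Those with 1 gene gave 22180 genes, of which 18964 were protein-coding and 1082 had over 1 probe set. Symbols were checked through gene identifiers against a RefSeq gene table of the mouse assembly GRCm38.p6, which held 23328 of the probe sets and changed 0 symbols. It was used for names and gene types only. The mean over a gene's probe sets was analysed. The plan had been to keep the probe set with the highest mean, and to test a filter on dim genes, but centred values give neither a meaning.

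All tests were moderated tests in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over the 22180 genes and an adjusted p below 0.05 as the threshold. A 24-h rhythm was tested with a cosine and a sine term, which also gave an amplitude (the peak minus the mean), a peak time and their standard errors (SE). The peak-to-trough fold is 2 to the power of 2 amplitudes. Any difference among the 6 times was tested with a moderated F over the time means. A 12-h component was tested in a fit that held the 24-h terms. Night against day compared the mean of ZT15, ZT19 and ZT23 with that of ZT03, ZT07 and ZT11, and dusk against dawn compared ZT11 and ZT15 with ZT23 and ZT03. The opposite times ZT15 and ZT03, ZT19 and ZT07, and ZT23 and ZT11 were compared as well. All contrasts came from 1 fit of the 24 arrays with 18 residual degrees of freedom. These tests, the gene lists and the rule for named genes were fixed before the data were examined. The comparisons of ZT03 with ZT23 and of ZT15 with ZT11 were added afterwards, chosen as the steps across lights-on and lights-off once all 6 steps between neighbouring times had been counted.

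There were 27 pathway lists and 15 lists of cell type markers. For each list the members with a 24-h rhythm were counted, over all genes and adjusted over the list alone, and set against the other genes with a two-sided Fisher's exact test. Shifts of a list were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. P-values were adjusted over the 42 lists in the Fisher tests, and over the 84 tests of lists and contrasts in camera. A list of 20 platelet genes, 17 of them measured, was added after the data had been seen. It holds 8 genes whose night values or whose values in ZT15 replicate 1 had already been seen, so results are also given for the other 9.

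Named genes were every measured member of the core clock list, the 12 largest amplitudes with a peak in the light phase and the 12 with a peak in the dark phase, and up to 5 genes with a 12-h component. Added to these were the 10 largest changes in each direction for night against day and dusk against dawn, the 5 largest in each direction for the other contrasts, and the 4 smallest cosinor p-values of each list. Predicted genes were not named. Further list members are given where a group is described. The plan to name the brightest markers of each cell type could not be followed without expression levels.

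Alternatives covered the replicate number as a block, quantile normalization, centring of each array, probe sets in place of genes, a robust trend in the prior variance, array weights, a stricter threshold of 0.01, ranks, a minimum peak-to-trough change of 1.5-fold, fits of only the arrays compared, and each array left out in turn. Leaving out the 3 arrays of lowest weight (ZT15 replicate 1, ZT23 replicate 4 and ZT07 replicate 4) and testing only protein-coding genes were chosen after the data had been seen. The tests were tried on simulated arrays with the spread of the real genes, in which 200 of 22180 genes were changed. Genes were drawn independently from normal distributions, so the false shares below leave out any correlation between genes. In 5 runs, 85.2% of the genes with a 1.3-fold rhythm and 98.8% of those with a 1.5-fold rhythm were recovered, and 4.57% of the calls were false. For night against day, 98.0% of genes with a 1.3-fold change were recovered, and 4.60% of the calls were false. Differences between mean values of lists were tested with 100000 permutations, two-sided. The number of arrays limits the precision of every value. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.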

Results

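Transcripts were profiled in mouse heart muscle over a single day, at ZT03, ZT07 and ZT11 in the light and at ZT15, ZT19 and ZT23 in the dark, with 4 arrays per time point. The comparisons address which heart transcripts change with the time of day, when each peaks, and how the dark phase differs from the light phase. Values are log2 differences from each gene's median over the 24 arrays, so levels of different genes cannot be compared.

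Of 22180 genes, 1688 (7.61%) had a 24-h rhythm in limma's moderated test, and their median peak-to-trough change was 1.24-fold. The times cover a single cycle, so a 24-h rhythm here is a pattern over that cycle, and its return was not tested. Effects of the light cycle and of the clock could not be told apart. No batch is given in the labels, so a batch shared by a time point's arrays could not be told from time either. Arntl, Nr1d1 and Dbp, all members of the core clock list, changed most among genes that peaked in the light. Ppbp, which encodes platelet basic protein, and Zbtb16, a zinc finger regulator, changed most among those that peaked in the dark. The change reached 1.5-fold in 169 genes and 2-fold in 36. Peaks of all 1688 genes were spread over the day, with 252 to 308 genes in each 4-h bin. Those of the 169 genes were less even, with 31, 18, 37, 43, 26 and 14 in successive bins from lights-on. The dark phase held 839 of 1688 peaks, or 49.7% (95% Clopper-Pearson interval 47.3 to 52.1%, which treats genes as independent). This share was 52.9% without ZT15 replicate 1 and 46.8% without ZT11 replicate 1. At an unadjusted p below 0.05 there were 4320 genes, where 1109 would pass by chance.

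**Figure D1:**
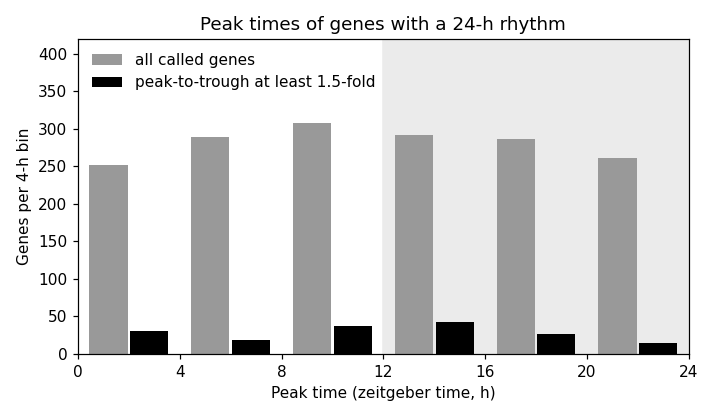
Number of genes with a 24-h rhythm by peak time, in 4-h bins of zeitgeber time, with the dark phase shaded; grey bars are all 1688 genes and black bars the 169 with a peak-to-trough change of at least 1.5-fold. Grey bars lie between 252 and 308 genes, and black bars between 14 and 43.

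Core clock genes included the 3 largest rhythms. Arntl, which encodes the CLOCK partner BMAL1, had an amplitude of 1.42 ± 0.065 (SE, 24 arrays), a 7.13-fold change, with its peak at ZT 0.329 ± 0.174 (SE, in h) (adjusted p = 2.47e-12). Its partners Clock (1.99-fold) and Npas2 (1.89-fold) peaked close to it, at ZT 0.835 and ZT 1.10. Nr1d1 and Nr1d2, which encode the REV-ERB repressors of Arntl, changed 5.52-fold and 3.46-fold with peaks at ZT 7.56 and ZT 10.5. Dbp (5.08-fold, ZT 11.4), Per1 (4.20-fold, ZT 11.2), Per3 (3.55-fold, ZT 12.0) and Ciart (2.85-fold, ZT 11.1) peaked around lights-off. Cry1, a repressor of CLOCK and BMAL1, peaked at ZT 18.3 (1.96-fold), and Nfil3, which competes with Dbp for its sites, at ZT 21.7 (1.78-fold). Bhlhe40 (1.54-fold) and Bhlhe41 (1.75-fold) peaked at ZT 10.3 and ZT 10.7, and Cry2 (1.56-fold), Tef (1.49-fold) and Hlf (1.76-fold) between ZT 13.0 and ZT 13.5. Arntl had a mean of 1.42 ± 0.12 (SD, n = 4) at ZT03 and -1.13 ± 0.16 at ZT11, and Dbp had -1.05 ± 0.20 and 1.15 ± 0.13. Of 20 measured members of the list, 17 were called, and 17 when adjusted over the list alone (Fisher's exact test, adjusted p = 3.43e-15). Rorb, Csnk1e and Fbxl21 were not called. The Rora call (1.17-fold, adjusted p = 0.0297) was lost without any of 7 of the 24 arrays, and Tef had a rhythm in only 1 of its 2 probe sets (adjusted p = 7.79e-09 and 0.516).

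**Figure D2:**
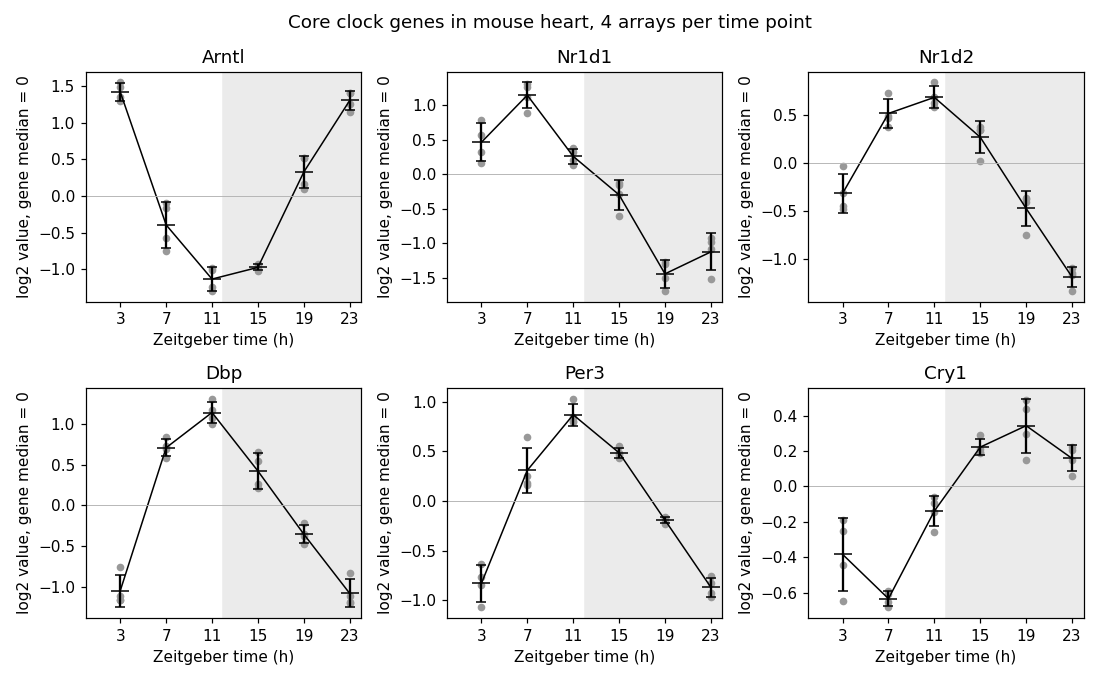
Log2 values of 6 core clock genes by zeitgeber time in h, each relative to the gene's median over 24 arrays; grey points are arrays, dashes with bars are the mean and SD of 4 arrays, and the dark phase is shaded. The lowest mean of Arntl is -1.13 at ZT11, the time at which Dbp is highest with 1.15.

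Outside the clock, the largest light-phase rhythms were those of Tcap, Pdk4 and Slc41a3. Tcap, a Z-disc protein that caps titin, changed 3.91-fold (amplitude 0.98 ± 0.054, peak at ZT 10.7, adjusted p = 4.42e-11). Pdk4, the kinase that inhibits pyruvate dehydrogenase, changed 2.94-fold with a peak at ZT 5.25, and Slc41a3, of a magnesium transporter family, 2.92-fold with a peak at ZT 2.34. Nppb, the gene of B-type natriuretic peptide (2.70-fold), and Spon2, a matrix protein gene (2.58-fold), peaked soon after lights-on. Of dark-phase genes, Ppbp changed 4.89-fold (amplitude 1.15 ± 0.206, adjusted p = 0.00213), and its values at ZT15 varied widely (SD 1.52). Zbtb16 (3.71-fold, ZT 13.5), the metallothionein Mt2 (3.38-fold, ZT 12.5), Rhobtb1 (2.60-fold, ZT 13.5) and Timp3, an inhibitor of metalloproteinases (2.38-fold, ZT 13.5), peaked early in the night. They were followed by the cell cycle kinase Wee1 (2.36-fold, ZT 14.6), Fmo2 (2.50-fold, ZT 15.5), Ier3 (2.15-fold, ZT 15.9), Angptl7 (2.10-fold, ZT 16.7) and the oxygen sensor Egln3 (2.56-fold, ZT 21.1). The deubiquitinase Usp2 (2.08-fold, ZT 13.1) and Trp53i11 (2.05-fold), which peaked just before lights-on, completed the set.

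Of the 42 lists, 23 passed the test for an excess of genes with a 24-h rhythm. Some rhythmic genes, such as Klf15, Foxo3 and Rcan1, stand on several lists, so these excesses are not independent of each other. Without the 3 arrays of lowest weight 18 of the 23 passed, and ion channels, immediate early genes, cell cycle, fibroblast and endothelial markers did not. The test treats genes as independent, and the other genes could not be limited to those expressed in heart. They include 1105 olfactory receptors (3 called) and 484 microRNA genes (11 called). Part of an excess may therefore come from listing genes that are expressed in heart. Glucocorticoid-responsive genes had 18 of 24 called (20 adjusted over the list alone, adjusted p = 1.22e-14), and 12 of the 18 peaked in the dark. Among the 18 were Fkbp5, a chaperone of the glucocorticoid receptor (1.66-fold, ZT 14.1), Klf9 (1.66-fold, ZT 10.8), Tsc22d3 (1.51-fold, ZT 14.4) and Per1, which is also on the clock list. Cytosolic heat shock genes had 13 of 24 called (14 adjusted over the list alone, adjusted p = 3.25e-08), with 12 peaks in the dark. The inducible HSP70 genes Hspa1b (1.99-fold, ZT 18.6) and Hspa1a (1.68-fold, ZT 18.4) and the co-chaperone Chordc1 (1.59-fold, ZT 20.4) were among them. The other member was Cirbp, a gene known to be induced by cold, which peaked at ZT 8.25 (1.51-fold). Genes of protein folding in the endoplasmic reticulum had 10 of 27 called (12 adjusted over the list alone, adjusted p = 8.43e-05). They were led by Herpud1, a gene of protein degradation at that membrane (2.05-fold, ZT 14.2), while Hspa5 (1.24-fold) and Pdia3 (1.26-fold) peaked near lights-on.

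Glucose uptake and glycolysis had 9 of 27 called (15 adjusted over the list alone, adjusted p = 0.000468), with 8 peaks in the light. These included the phosphofructokinase Pfkm (1.27-fold, ZT 9.10) and the insulin-responsive glucose transporter Slc2a4 (1.19-fold, ZT 10.5), whereas the lactate transporter Slc16a1 peaked at ZT 18.7 (adjusted p = 0.000318). PPAR-responsive fuel genes had 6 of 20 called (9 adjusted over the list alone, adjusted p = 0.00824), among them Pdk4, the mitochondrial carrier Ucp3 (2.11-fold, ZT 5.87) and Angptl4 (1.80-fold, ZT 3.23). Insulin and nutrient signalling had 9 of 29 (13 adjusted over the list alone, adjusted p = 0.000791), from Irs1 at ZT 1.36 (1.38-fold) to Pik3r1 at ZT 14.6 (1.63-fold). Glycogen genes had 5 of 17 called (5 adjusted over the list alone, adjusted p = 0.0179). The glycogen-targeting subunits Ppp1r3a (1.43-fold, ZT 16.4), Ppp1r3b (1.60-fold, ZT 17.6) and Ppp1r3c (1.80-fold, ZT 21.5) peaked in the dark, Ppp1r3b in 1 of its 2 probe sets (adjusted p = 2.29e-08 and 0.0811). Triglyceride genes had 5 of 23 called (8 adjusted over the list alone, adjusted p = 0.0499), with Dgat2, an enzyme of triglyceride synthesis, at ZT 14.3 (1.69-fold), and the excess was lost without ZT11 replicate 1 (adjusted p = 0.0658). NAD and redox genes had 8 of 32 called (12 adjusted over the list alone, adjusted p = 0.00669), all with dark-phase peaks, such as Gsta3 (1.55-fold, ZT 16.7), Gclm (1.33-fold, ZT 15.9) and Nampt (1.29-fold, ZT 14.6). This excess was lost without ZT07 replicate 2 (adjusted p = 0.133), ZT07 replicate 4 (adjusted p = 0.123) or ZT15 replicate 3 (adjusted p = 0.113). Autophagy and atrophy genes had 9 of 27 (11 adjusted over the list alone, adjusted p = 0.000468), with the ubiquitin ligases Trim63 (1.54-fold, ZT 5.26) and Fbxo32 (1.55-fold, ZT 7.34) high in the light.

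Sarcomere genes had 10 of 25 called (14 adjusted over the list alone, adjusted p = 4.93e-05), and 9 of the 10 peaked in the light. Myom2 (1.39-fold, ZT 7.47), Lmod2 (1.36-fold, ZT 9.48) and Mybpc3 (1.26-fold, ZT 8.20) stood beside Tcap, whereas Myot peaked in the dark (1.46-fold). Cardiac stress and growth genes had 10 of 25 (16 adjusted over the list alone, adjusted p = 4.93e-05), led by Nppb, by Rcan1, an inhibitor of calcineurin (2.56-fold, ZT 0.559), and by Ankrd23 (2.08-fold, ZT 1.07). Calcium handling had 8 of 26 (9 adjusted over the list alone, adjusted p = 0.00161), including the sodium-calcium exchanger Slc8a1 (1.44-fold, ZT 4.97) and the phosphodiesterase Pde3a (1.48-fold, ZT 3.06). Ion channels and connexins had 6 of 24 (6 adjusted over the list alone, adjusted p = 0.0183), with the connexin Gja1 at ZT 1.53 (1.68-fold) and the potassium channels Kcnj5 (ZT 19.3) and Kcnh2 (ZT 10.5). The Kcnh2 call was lost without ZT11 replicate 4 or ZT23 replicate 2, and 4 of the 6 were called without the 3 arrays of lowest weight, where the list had no excess (adjusted p = 0.196). The excess was also lost without ZT11 replicate 4, ZT15 replicate 1 or ZT15 replicate 4 alone (adjusted p up to 0.123).

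Extracellular matrix genes had 14 of 28 called (18 adjusted over the list alone, adjusted p = 3.25e-08). The 10 light-phase peaks included Col1a1 (1.36-fold, ZT 6.29), Col3a1 (1.40-fold, ZT 6.24), Col4a2 (ZT 6.06) and the metalloproteinase Mmp14 (1.57-fold, ZT 3.04). The metalloproteinase inhibitors Timp3, Timp4 (1.85-fold, ZT 12.8) and Timp2 (1.18-fold, ZT 14.5) peaked after lights-off. Vascular genes had 8 of 26 (11 adjusted over the list alone, adjusted p = 0.00161). The receptors of vascular endothelial growth factor lay apart, Kdr at ZT 2.23 (1.59-fold) and Flt1 at ZT 13.8 (1.38-fold). Immediate early genes had 6 of 22 (7 adjusted over the list alone, adjusted p = 0.0130), with Egr1 at ZT 3.13 (1.46-fold) and Zfp36 at ZT 9.44 (1.44-fold), and 4 of the 6 were called without the 3 arrays of lowest weight. The list's excess was lost there (adjusted p = 0.159) and without ZT15 replicate 1 alone (adjusted p = 0.0675). Interferon and inflammatory genes had 6 of 26 (9 adjusted over the list alone, adjusted p = 0.0236), with the acute phase gene Serpina3n at ZT 19.4 (1.46-fold), an excess lost without any of 6 of the 24 arrays (adjusted p up to 0.174). Cell cycle genes had 6 of 31 (7 adjusted over the list alone, adjusted p = 0.0499), led by Wee1 and by the inhibitor Cdkn1a at ZT 22.8 (1.82-fold), and only 3 of them were called without the 3 arrays of lowest weight (list adjusted p = 0.991). Their excess was lost without any of 19 of the 24 arrays (adjusted p up to 0.296).

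The lists of central mitochondrial metabolism and translation held no excess of rhythmic genes. Of the tricarboxylic acid cycle 0 of 17 were called in limma's test (0 adjusted over the list alone), with Idh2 (1.09-fold, adjusted p = 0.0611) closest. Oxidative phosphorylation had 4 of 65 called (4 adjusted over the list alone, adjusted p = 1), all with dark-phase peaks, such as Cox6a1 (1.20-fold, ZT 19.3). Of fatty acid oxidation genes 2 of 21 were called (4 adjusted over the list alone, adjusted p = 0.973), namely Cpt1a, which admits fatty acids to mitochondria (1.58-fold, ZT 8.83), and Etfa (1.19-fold). Sterol and fatty acid synthesis had 3 of 21 (8 adjusted over the list alone, adjusted p = 0.371) and branched-chain amino acid catabolism 3 of 25 (4 adjusted over the list alone, adjusted p = 0.701). Ribosomal proteins had 3 of 56 (3 adjusted over the list alone, adjusted p = 1) and ribosome biogenesis 4 of 34 (8 adjusted over the list alone, adjusted p = 0.546).

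**Figure D3:**
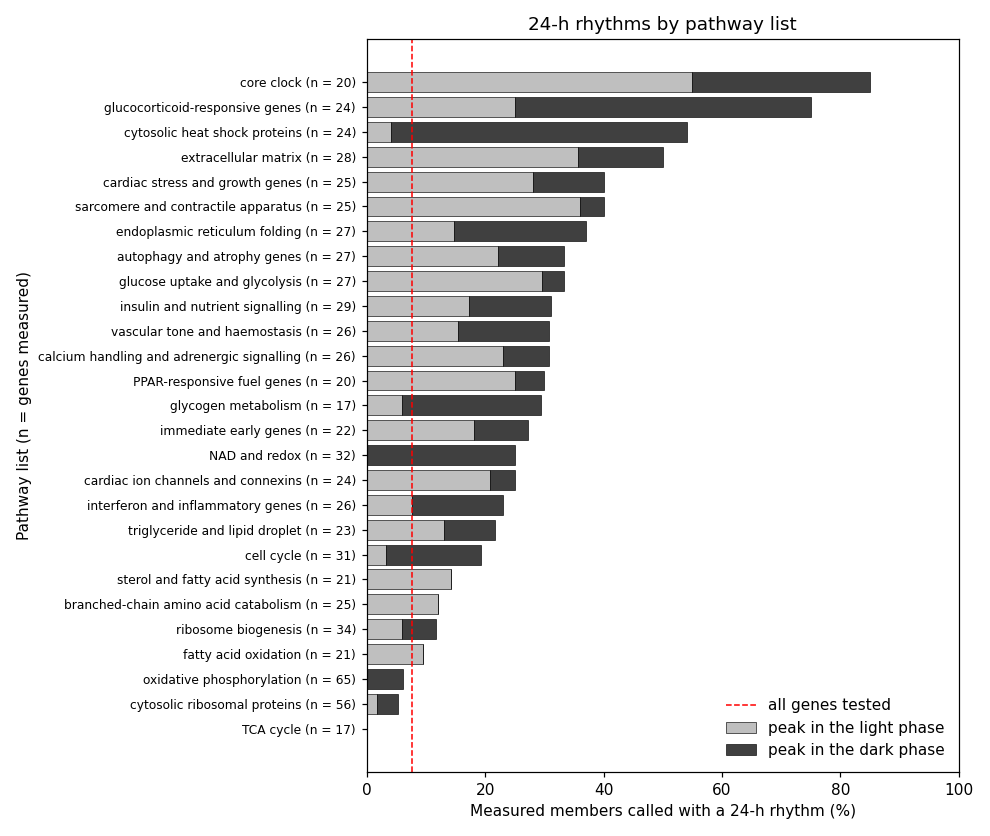
Percentage of the measured genes of each pathway list with a 24-h rhythm, split by light-phase (light grey) and dark-phase (dark grey) peaks; n is the number of genes measured and the dashed line is the 7.61% of all genes. The core clock list reaches 85% and the tricarboxylic acid cycle 0%.

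Among cell type markers, macrophage genes had 7 of 12 called (9 adjusted over the list alone, adjusted p = 4.93e-05), all with peaks in the dark. Lyve1, a marker of resident macrophages and lymphatic vessels, changed 1.98-fold (ZT 16.8), C1qb, a complement gene, 1.53-fold (ZT 18.5), and the scavenger receptor Cd163 peaked at ZT 12.8 (adjusted p = 0.000297). Without the 3 arrays of lowest weight 5 of the 12 were called (list adjusted p = 0.00459). Fibroblast and endothelial markers had 4 of 12 called each (6 adjusted over the list alone in both, adjusted p = 0.0212). The fibroblast genes Dcn (1.24-fold, ZT 18.7) and Col1a1 differed in phase by about 12 h, and only 2 of the 4 fibroblast calls and 3 of the 4 endothelial calls were left without those 3 arrays, where neither list had an excess (adjusted p = 0.402 and adjusted p = 0.128). The fibroblast excess was also lost without any of 6 of the 24 arrays, and the endothelial one without ZT15 replicate 1 or ZT15 replicate 3. Ventricular cardiomyocyte markers had 1 of 12 called, Ryr2 (1.12-fold, ZT 5.53, adjusted p = 0.00910). No gene was called among the measured markers of atrial cardiomyocytes (8), smooth muscle and pericytes (10), neutrophils (11), lymphocytes (9), red cells (3), adipocytes (10), skeletal muscle (10), lung (8), thymus (6), Schwann cells and neurons (8) or mesothelium (7). Adjusted over the list alone, 4 atrial and 5 smooth muscle markers were called. The median night minus day difference was 0.136 for the atrial list and 0.139 for the macrophage list. Camera did not call the atrial list (adjusted p = 0.0739 at the preset correlation, 0.548 estimated). A different share of atrial tissue in night and day samples was therefore not excluded.

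Testing any difference among the 6 times called 1046 genes (3724 at an unadjusted p below 0.05), and 901 of them also had a 24-h rhythm. The other 145 included genes with a single high or low time. Ppp1r10, a nuclear phosphatase subunit chosen after its values were seen, had a mean of 0.46 ± 0.11 (SD, n = 4) at ZT11 and between -0.14 and 0.05 at the other times (adjusted p = 0.00192). The immune receptor gene Clec7a, chosen in the same way, had 0.42 ± 0.24 at ZT03 and at most 0.07 elsewhere (adjusted p = 0.00645). In limma's test of a 12-h component 0 genes passed, with 1402 at an unadjusted p below 0.05, and up to 5 passed in other settings, namely Ciart, Dbp, Ppp1r15b, Spon2 and Gabarapl1.

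Night differed from day in 973 genes, 420 higher and 553 lower. Ppbp was 3.24-fold higher at night (log2 1.70 ± 0.286, SE, 12 arrays against 12, adjusted p = 0.000949). Egln3 (1.71-fold), Hspa1b (1.67-fold), Ceacam1, a cell adhesion gene (1.57-fold), Cry1 (1.54-fold), Angptl7 (1.54-fold), Ctla2a (1.53-fold), Ier3 (1.53-fold), the platelet glycoprotein gene Gp9 (1.51-fold) and Hspa1a (log2 0.59 ± 0.063) were also higher. Nr1d1 was 2.98-fold lower (log2 -1.58 ± 0.082, adjusted p = 1.46e-10), followed by Pdk4 (1.91-fold), Ucp3 (1.72-fold), the immediate early gene Nr4a1 (1.70-fold), Lncpint, a long noncoding RNA (1.70-fold), Nr1d2 (1.69-fold) and Tcap (1.66-fold). Txnip, an inhibitor of glucose uptake (1.64-fold), Scin (1.60-fold) and the splicing factor Srsf5 (1.56-fold) completed the set. The Nr4a1 call (adjusted p = 0.0285) was lost without any of 5 of the 24 arrays. Without the 3 arrays of lowest weight the balance turned, with 566 genes higher and 517 lower.

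As groups, heat shock genes rose at night, with 11 of 24 higher and only Cirbp lower (camera, adjusted p = 1.40e-11 preset and adjusted p = 0.000878 with an estimated correlation). Sarcomere genes fell, with 9 of 25 lower and Myot higher (adjusted p = 1.35e-07, and adjusted p = 0.0335 with an estimated correlation). Their call with the estimated correlation was lost without any of 8 of the 24 arrays (adjusted p up to 0.0529) and without the 3 arrays of lowest weight (adjusted p = 0.0905). Autophagy (7 of 27 lower, 1 higher) and insulin signalling (5 of 29 lower) fell at the preset correlation (adjusted p = 0.000877 for both), but had adjusted p = 0.402 and adjusted p = 0.342 with an estimated correlation. PPAR-responsive genes (4 of 20 lower, adjusted p = 0.00814, estimated 0.522), extracellular matrix (8 of 28 lower, Bgn higher, adjusted p = 0.0148, estimated 0.577), glycolysis (5 of 27 lower, Slc16a1 higher, adjusted p = 0.0243, estimated 0.577) and the core clock (7 of 20 lower, 3 higher, adjusted p = 0.0226, estimated 0.271) were called at the preset correlation only. Without the 3 arrays, 3 of these calls were lost, namely those of PPAR-responsive genes (adjusted p = 0.1003), glycolysis (adjusted p = 0.0634) and the core clock (adjusted p = 0.0845). Leaving out 1 array ended the call of glycolysis (4 of the 24 arrays), the core clock (ZT15 replicate 1) and extracellular matrix (ZT11 replicate 4). Over the same contrast, macrophage markers were higher in 5 of 12 and lower in 0 (adjusted p = 1.11e-05, estimated 0.107), fibroblast markers in 2 of 12 higher, with Col1a1 lower (log2 -0.27, adjusted p = 0.00339; list adjusted p = 0.0282, estimated 0.548), and ventricular cardiomyocyte markers in 1 of 12 lower (adjusted p = 0.0341, estimated 0.522). The fibroblast call was lost without the 3 arrays (adjusted p = 0.133) and without any of 5 of the 24 arrays, and the cardiomyocyte call without any of 9. Of 17 measured genes of the platelet list, which was drawn up after the data had been seen, 11 were higher at night. The 17 include 8 genes whose values had been seen before, and 5 of the other 9, measured in the same arrays, were higher at night.

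**Figure D4:**
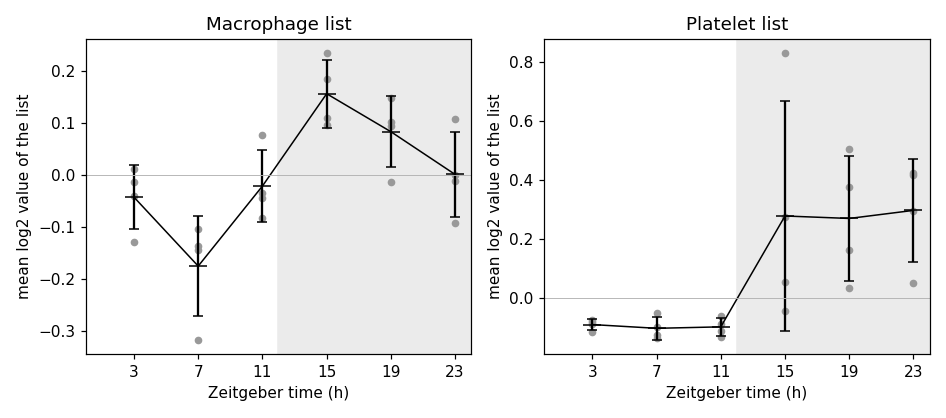
Mean log2 value of the 12 macrophage markers and of the 17 platelet genes by zeitgeber time in h; grey points are arrays, dashes with bars are the mean and SD of 4 arrays, and the dark phase is shaded. Platelet means lie between -0.14 and -0.05 in the 12 light-phase arrays and between -0.05 and 0.83 in the 12 dark-phase arrays.

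Dusk differed from dawn in 834 genes, 457 higher and 377 lower. Dbp was 3.61-fold higher at dusk (log2 1.85 ± 0.076, SE, 8 arrays against 8, adjusted p = 5.74e-13). Zbtb16 (3.09-fold), Per1 (3.03-fold), Per3 (2.88-fold), Mt2 (2.84-fold), Tcap (2.64-fold), Nr1d2 (2.35-fold), Rhobtb1 (2.27-fold), Ciart (2.21-fold) and Timp3 (2.11-fold) were also higher. Arntl was 5.34-fold lower (log2 -2.42 ± 0.087, adjusted p = 7.95e-14), followed by Slc41a3 (2.39-fold), Nppb (2.35-fold), Spon2 (2.27-fold), Rcan1 (2.25-fold) and Rrad, a small GTPase that restrains calcium channels (2.02-fold). Epha4 (1.92-fold), Ankrd23 (1.89-fold), Trp53i11 (1.82-fold) and Clock (1.81-fold) were lower as well. Glucocorticoid-responsive genes were higher at dusk in 14 of 24 and lower in 3 (camera, adjusted p = 3.27e-13, and adjusted p = 0.0335 with an estimated correlation). The latter call was lost without any of 4 of the 24 arrays (adjusted p up to 0.0557) and without the 3 arrays of lowest weight (adjusted p = 0.0905). The core clock had 11 of 20 higher and 4 lower (adjusted p = 8.26e-10, and adjusted p = 0.00101 with an estimated correlation). Lower at the preset correlation only were cardiac stress genes (adjusted p = 0.00560, estimated 0.427), calcium handling (adjusted p = 0.0170, estimated 0.267), sterol synthesis (adjusted p = 0.0282, estimated 0.427) and endoplasmic reticulum folding (adjusted p = 0.0426, estimated 0.522). The call of sterol synthesis was lost without any of 4 of the 24 arrays, and that of endoplasmic reticulum folding without any of 9. In each of the 17 camera calls, the list's median had the sign of the test.

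Between opposite times, ZT15 and ZT03 differed in 679 genes, 302 higher and 377 lower at ZT15. Zbtb16 was 3.82-fold higher (log2 1.93 ± 0.230, SE, n = 4 each, adjusted p = 2.07e-05), and Dbp (2.78-fold), Ier3 (2.59-fold), Per3 (2.49-fold) and Fmo2 (2.35-fold) were higher too. Arntl (5.26-fold), Slc41a3 (3.02-fold), Txnip (2.72-fold), Pdk4 (2.46-fold) and Rrad (2.41-fold) were lower. The balance turned without the 3 arrays of lowest weight, with 309 higher and 303 lower, and without ZT15 replicate 1, with 266 and 263. ZT23 and ZT11 differed in 604 genes, 214 higher and 390 lower at ZT23, and in 356 without ZT11 replicate 4. Arntl (5.42-fold), Ppbp (3.87-fold), Nppb (2.61-fold), Egln3 (2.33-fold) and Trp53i11 (2.27-fold) were higher, and Dbp (4.69-fold), Per1 (4.01-fold), Tcap (3.73-fold), Mt2 (3.71-fold) and Nr1d2 (3.67-fold) lower. The Ppbp call (adjusted p = 0.0342) was lost without any of 7 of the 24 arrays.

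ZT19 and ZT07 differed in 353 genes, 197 higher and 156 lower at ZT19. Egln3 (2.18-fold), Cry1 (1.97-fold), Fmo2 (1.85-fold), the purinergic receptor gene P2ry1 (1.78-fold) and the complement gene C7 (1.76-fold) were higher. Nr1d1 was 6.00-fold lower (log2 -2.58 ± 0.142, SE, n = 4 each, adjusted p = 4.34e-10), followed by Pdk4 (2.62-fold), Tcap (2.28-fold), Dbp (2.09-fold) and Per1 (2.00-fold). The Per1 call (adjusted p = 0.0491) was lost without any of 16 of the 24 arrays, the Egln3 call without ZT07 replicate 4 or ZT19 replicate 4, and the C7 call without ZT07 replicate 4. The count fell to 168 without ZT07 replicate 4, 187 without ZT19 replicate 2, 224 without ZT19 replicate 1 and 233 without ZT07 replicate 3.

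Across lights-on, ZT03 differed from ZT23 in 152 genes, 124 higher and 28 lower at ZT03. Nr1d1 (3.00-fold, log2 1.59 ± 0.142, SE, n = 4 each, adjusted p = 5.26e-06), Txnip (2.44-fold), Nr1d2 (1.83-fold), the matricellular gene Ccn1 (1.79-fold) and Scin (1.75-fold) were higher. Ier3 (1.71-fold), Gpr22 (1.57-fold), Cry1 (1.46-fold), Noxred1 (1.43-fold) and the constitutive chaperone Hspa8 (1.42-fold) were lower. Across lights-off, ZT15 differed from ZT11 in 45 genes, 25 higher and 20 lower at ZT15. Hspa1b (1.96-fold, adjusted p = 0.0174), Hspa1a (1.89-fold, adjusted p = 0.000767), Angptl7 (1.81-fold), Ppp1r3c (1.57-fold) and the chaperone Hsph1 (1.51-fold) were higher. Ciart (1.74-fold), Dbp (1.65-fold), Ppp1r10 (1.51-fold), Srsf5 (1.47-fold) and Ednrb, an endothelin receptor gene (1.38-fold), were lower. The other steps between neighbouring times called 45 (ZT07 against ZT03), 69 (ZT11 against ZT07), 45 (ZT19 against ZT15) and 15 genes (ZT23 against ZT19). At lights-on, leaving out 1 array ended the calls of Noxred1 (5 of the 24 arrays), Hspa8 (4) and Ier3 (ZT23 replicate 4). At lights-off it ended those of Ppp1r3c (6), Ednrb (6), Hspa1b (4) and Angptl7 (ZT11 replicate 2 or ZT15 replicate 3). The lights-on count was 51 without ZT23 replicate 4, 63, 73 and 94 without ZT03 replicates 3, 4 and 2, and 86 without the 3 arrays of lowest weight. The lights-off count was 15 and 27 without ZT11 replicates 3 and 2, and 25 without ZT15 replicate 3. At an adjusted p below 0.01 it was 13, with 6 higher and 7 lower. Without ZT11 replicate 1 it was 70 and the balance turned, with 24 higher and 46 lower, whereas it was 74 without the 3 arrays, with 50 higher and 24 lower.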

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

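The comparison of small nuclear and nucleolar RNA was chosen only after the result was seen. In 37 named genes with large rhythms or on the clock list, and in the spread of each array, 15 of 228 groups of 4 arrays held 1 array whose gap to its nearest neighbour took more of the group's range than Dixon's 95% critical value allows. Chance gives about 1 in 20, or 11.4 groups. The gap was 0.9384 of the range for Cry2, a clock repressor, in ZT19 replicate 1 (0.20, others -0.018 to -0.0044). It was 0.896 for Nr1d2 in ZT15 replicate 1 (0.02, others 0.34 to 0.38) and 0.8707 in ZT19 replicate 4 (-0.74, others -0.41 to -0.36). Dbp stood apart in ZT03 replicate 4 (0.8654; -0.76, others -1.17 to -1.11), Zbtb16 in ZT15 replicate 4 (0.8514; 0.39, others 1.05 to 1.16) and Spon2 in ZT11 replicate 4 (0.8879; -0.38, others -0.18 to -0.15). At ZT23 there were gaps for Ciart (0.8808) and Ier3 (0.8651) in replicate 4, Nfil3 (0.9385) and Mt2 (0.846) in replicate 3, Slc41a3 (0.8634) in replicate 1 and Timp3 (0.9127) in replicate 2, and at ZT19 for Usp2 (0.8661) in replicate 1. The spread of all probe sets stood apart in ZT07 replicate 4 (0.8306; SD 0.153, others 0.103 to 0.112) and in ZT15 replicate 1 (0.8291; SD 0.171, others 0.112 to 0.122).

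ZT15 replicate 1 had the widest spread of the 24 arrays. A wrong sampling time is argued against: its clock genes read a time 1.1 h from its label, where the other arrays were up to 1.9 h off and the median was 0.65 h. The median deviation of 86 small nuclear and nucleolar RNA genes was 0.269 in this array and between -0.18 and 0.108 in the other 23, so a larger content of small RNA is a candidate explanation for part of the spread. No biological explanation was tested for this array.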

How the results depend on the processing

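Protein-coding genes alone and the fits without the 3 arrays of lowest weight were chosen only after the data had been seen. So were the camera tests with 1 array left out and all alternatives for the number of enriched lists. The comparisons of ZT03 with ZT23 and ZT15 with ZT11 were also chosen then. Of 278 results for 208 named genes, 0 reversed. Calls were lost for 1 with quantile normalization, 0 with centred arrays, 2 with a robust trend, 1 with array weights, 37 at an adjusted p below 0.01 and 12 without the 3 arrays. Over 6672 values with 1 array left out, 100 calls were lost and 28 gained. The 24-h rhythm was called in 1639 to 1952 genes in the settings with scaling, trend, weights, probe sets or protein-coding genes changed, and in 1728 without the 3 arrays, 1408 of them shared. At an adjusted p below 0.01 the counts were 854 (24-h), 513 (any difference), 444 (night against day), 440 (dusk against dawn), 324 (ZT15 against ZT03), 116 (ZT19 against ZT07), 293 (ZT23 against ZT11), 36 (ZT03 against ZT23) and 13 (ZT15 against ZT11), where a stricter threshold can only lower them. With genes called at that threshold, and lists held to an adjusted p below 0.01 as well, 11 lists were enriched. The stricter list threshold alone removes main calls with a list adjusted p above 0.01. The effect of the gene threshold was not tested apart from it. The 24-h count was 1068 with ranks, whose cause was not tested, and 169 with a 1.5-fold minimum, which removes smaller rhythms. With only the 8 arrays compared, which leaves fewer arrays, the counts were 374 (ZT15 against ZT03), 178 (ZT19 against ZT07), 387 (ZT23 against ZT11), 65 (ZT03 against ZT23) and 5 (ZT15 against ZT11: Hspa1a, Hspa1b, Ppp1r3b, Ppp1r3c and Rnasek). For the 12-h component 4 genes passed with arrays centred on the median, 4 with array weights and 5 among protein-coding genes only, and the cause was not tested. Of the camera calls, 4 of 17 held with the estimated correlation of the gene lists. In the called lists it lay between 0.0306 (calcium handling) and 0.217 (fibroblast markers), above the preset 0.01, and a larger correlation weakens camera's test. Of the 4 calls, 2 held without the 3 arrays of lowest weight (heat shock genes at night and the core clock at dusk), and the cause was not tested. At the preset correlation 14 were called without those arrays, with 13 of the 17 kept, 4 lost (core clock, PPAR-responsive genes, glycolysis and fibroblast markers at night) and 1 gained (glycogen genes, higher at night, adjusted p = 0.0306). Of the 23 lists with an excess of 24-h genes, 18 were kept there, 5 lost and 0 gained. Without the 3 arrays of lowest weight, ZT03 against ZT23 gave 86 genes, ZT15 against ZT11 gave 74, and 53.3% of peaks lay in the dark, and the cause was not tested. With 1 array left out the ranges were 1445 to 1829 (24-h), 895 to 1134 (any difference), 0 to 3 (12-h), 765 to 1243 (night against day), 697 to 884 (dusk against dawn), 455 to 724 (ZT15 against ZT03), 168 to 465 (ZT19 against ZT07), 356 to 698 (ZT23 against ZT11), 51 to 187 (ZT03 against ZT23), 15 to 70 (ZT15 against ZT11), 46.8 to 52.9% (peaks in the dark), 18 to 23 (enriched lists) and 14 to 19 (camera calls). The low ends came without ZT07 replicate 4 (168), ZT11 replicate 4 (356), ZT23 replicate 4 (51) and ZT11 replicate 3 (15). The 12-h count was 3 without ZT03 replicate 1 or ZT15 replicate 3, 2 without ZT07 replicate 4 or ZT23 replicate 3, and 1 without ZT23 replicate 1. Same-numbered arrays did not deviate together (mean residual correlation -0.0141 over 60 pairs, from -0.228 to 0.226), and 6 of 24 arrays correlated best with their own number. With the replicate number as a block the 24-h count was 1576, of which 1512 were shared, night against day gave 912 genes, dusk against dawn 791 and ZT03 against ZT23 110, while no count of genes moved by over 1.5 times, and 5 calls of named genes were lost and 1 gained. The camera calls were 17 with that block at the preset correlation and 2 at the estimated one (heat shock genes at night and the core clock at dusk), where sarcomere genes at night and glucocorticoid-responsive genes at dusk had an adjusted p of 0.0614 each. Filters on dim genes and the probe set with the highest mean were not run, since centred values keep no level. Signal over background is unknown, so genes near the background cannot be set apart.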

Other observations

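The gene families, the single arrays and the platelet genes were chosen only after the data had been seen, as were the macrophage tests against other cell types and for separate peak times. Among 23 families defined by the start of the gene symbol, rhythmic genes were over-represented in those named Hsp (12 of 28, Fisher's exact test, adjusted p = 4.02e-06; mostly heat shock genes, but also Hspg2, the gene of the matrix proteoglycan perlecan), Kruppel-like factors (6 of 17, adjusted p = 0.00658), collagens (9 of 44, adjusted p = 0.024) and ubiquitin-specific proteases (10 of 56, adjusted p = 0.0344). Of the Kruppel-like factors, which are zinc finger regulators, Klf9 (1.66-fold), Klf15 (adjusted p = 0.00153), Klf13 (1.29-fold), Klf6 (1.28-fold) and Klf2 (1.33-fold) peaked between ZT 10.6 and ZT 13.1, and Klf7 (1.16-fold) at ZT 18.4. All 9 collagens peaked in the light, from Col5a2 at ZT 3.00 to Col6a2 at ZT 6.76. Olfactory receptors (3 of 1105, adjusted p = 5.52e-33) and microRNA genes (11 of 484, adjusted p = 4.16e-06) were under-represented. Genes not expressed in heart could not be left out, and a family with many of them may be under-represented for that alone. The over-represented families were set against the same background. Solute carriers (40 of 361, adjusted p = 0.0526), J-domain co-chaperones (7 of 41, adjusted p = 0.0856) and heterogeneous nuclear ribonucleoproteins (4 of 19, adjusted p = 0.0989) did not pass the threshold.

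Some genes differed among the times without a 24-h rhythm. Plk2, a kinase, had a mean of 0.43 ± 0.13 (SD, n = 4) at ZT03 and at most 0.23 at the other times (limma, adjusted p = 0.00213 for any difference and adjusted p = 0.144 for the 24-h rhythm). Ppp1r15b, which directs phosphatase 1 to the initiation factor eIF2, differed by small amounts, from -0.15 at ZT23 to 0.12 at ZT07 (adjusted p = 0.00170 and adjusted p = 0.345). In single arrays, Nnt, a mitochondrial transhydrogenase, was -2.18 in ZT19 replicate 2 and between -0.71 and 0.24 in the other 23. In ZT11 replicate 3, Igtp was 1.45 (others up to 0.56), Irgm2 1.27 (0.59), Gbp10 1.25 (0.50) and Cxcl9 1.00 (0.55), genes picked for these values. Ppbp was 3.33 in ZT15 replicate 1 (others up to 2.29), and Cd226 was 1.29 there (others up to 0.62).

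Platelet genes were higher at night. Their list mean was 0.38 higher over 17 genes, the 12 night arrays lay above every day array, and 8 of the 17 had a 24-h rhythm. The 9 genes not seen beforehand differed by 0.20 (permutation p = 2e-05), with 10 of 12 night arrays above every day array, among them Mmrn1 (1.21-fold, adjusted p = 9.20e-05) and Pf4 (1.19-fold, adjusted p = 0.0374) but not Itga2b (1.12-fold, adjusted p = 0.124). ZT15 replicate 1 alone is argued against, since the 9 genes differed by 0.18 without it (permutation p = 3e-05). Blood left in the heart could not be told apart: within time points the platelet and red cell means had r = 0.498 (permutation p = 0.157) and rho = 0.287 (permutation p = 0.236), r = 0.107 without the 2 arrays farthest from the median, and only 3 red cell genes were measured. Other blood cell lists had median night minus day differences of -0.035 (neutrophils), 0.0050 (lymphocytes) and 0.052 (red cells), against 0.28 for the platelet list. Camera at the preset correlation called none of these 3 (adjusted p = 0.397, 0.896 and 0.298). Whether their markers lie above background is unknown, so this leaves blood in the heart open. A change in circulating platelets or in how night hearts were collected may also give higher platelet values at night, and both were untested.

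Macrophage markers were also higher at night, by 0.16 in the list's mean (permutation p = 0.00047), with 10 of 12 genes above 0. A lower share of cardiomyocytes is argued against as the whole cause, since macrophage markers rose above the mean of fibroblast, endothelial and smooth muscle markers by 0.15 (permutation p = 4e-04), and above each list by 0.10 (permutation p = 0.00764), 0.19 (permutation p = 0.00043) and 0.17 (permutation p = 0.00049). A part stays open, as ventricular cardiomyocyte markers fell by 0.042 (permutation p = 0.0116, adjusted p = 0.0466 over 4 lists), while fibroblast markers differed by 0.064 (permutation p = 0.088, adjusted p = 0.176); at the preset correlation only, camera called them down and up, calls lost without any of 9 and 5 of the 24 arrays. The 3 arrays of lowest weight did not account for it (0.14 without them, permutation p = 0.00132). The 7 called markers, chosen by their rhythm in these data, peaked from Cd163 at ZT 12.8 to Adgre1 at ZT 21.4. A shared peak time fitted worse (permutation p = 1e-04, the smallest that 10000 permutations give). The permuted residuals came from the fit with separate peaks, which tends to lower this p. It argues only against a uniform macrophage population whose number sets all 7 markers. Changes in number were not excluded, since Lyve1 also marks lymphatic vessels and subsets could change at different times. A change in macrophage state with time, alone or with number, may be involved, as a hypothesis from the same data.

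For the 24-h rhythm, any difference, night against day and dusk against dawn, other splits of the arrays argue against chance. The smallest share that 100 splits can give is 0.01, with no allowance for the number of tests. For these and for the pairs of opposite times, 1 split, the real one, gave as many genes. The real and highest other counts were 1688 and 57 (24-h), 1046 and 23 (any difference), 973 and 10 (night against day) and 834 and 1 (dusk against dawn) over 100 splits each. Over 35 splits each they were 679 and 1 (ZT15 against ZT03), 353 and 0 (ZT19 against ZT07) and 604 and 5 (ZT23 against ZT11). The smallest share that 35 splits can give is 0.0286, with no allowance for the number of pairs. For the pairs too, chance was therefore argued against but not excluded. ZT03 against ZT23 and ZT15 against ZT11 were chosen after the counts of all 6 steps had been seen, and 35 splits are too few for a share below 0.05 once that choice is allowed for. Their real and highest other counts were 152 and 1, and 45 and 7. For the 12-h component, 11 of 100 splits gave at least the real 1402 genes at an unadjusted p below 0.05, with 2012 the highest, so chance was not excluded.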
